A study of Mus musculus with 13 samples.

How the data were processed

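The series held 13 samples from freshly isolated hepatocytes of adult C57Bl6 mouse liver. Gene deletion was induced in vivo by tamoxifen in floxed mice carrying the inducible Cre recombinase TTR-CreERT. Poly-A RNA was sequenced from 8 libraries in 4 groups of 2, and chromatin from 5 libraries, each of which pooled the DNA of a pair of mice. The activated group had lost Apc, a brake on β-catenin, and was sampled on day 6 after 1 injection of 1.5 mg tamoxifen. The null group had lost β-catenin (Ctnnb1) and was sampled on day 21 after 3 injections of 1.5 mg. The control group had no Cre and held 1 library with the Apc allele on the first schedule and 1 library with the β-catenin allele on the second. The wild type group carried the floxed Apc allele without Cre and was not injected. Day, number of injections and genotype therefore changed together between the activated and the null group and cannot be told apart there. The 2 control libraries differ in allele and schedule, so their spread includes these differences. Each mutant group shares its floxed allele and schedule with only 1 of them. For the other groups the labels do not say whether the libraries came from separate mice. Some gene lists described below differed between the 2 libraries of a group. The median log2 difference (library with more reads minus the other) of Kupffer cell markers was −2.97 in activated and −1.03 in null libraries. That of acute phase genes in wild type libraries was 0.83. These values argue against repeated sequencing of 1 RNA sample, but they do not show separate mice. P-values of tests on single genes measure only the spread between these samples.

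The RNA data were 6 tables, each comparing 2 groups over 36817 Ensembl mouse genes and 5 summary rows, made with DESeq on build mm9 per the submitters' processing notes, which give no version. The aligner and the counter are not given in the sources used here. Each table holds, per the file headers, a mean signal per group, a log2 fold change, a p-value, an adjusted p-value and a variance score for each group. The signal deposited by the authors was found, from the values, to be the mean over the group's 2 libraries of the gene's reads divided by all reads of that library, including reads outside genes, on several genes or without a unique alignment. The log2 fold change deposited by the authors is the logarithm of the ratio of these means, so it is scaled by total reads and not by gene reads. Its sign was turned here where needed so that a positive value means higher in the group named first. Symbols came from a gene name table for 31841 of the 36817 genes. No gene positions of build mm9 were used here, so genes carry no coordinates.

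The main result for each comparison was the authors' call at an adjusted p below 0.05, as fixed for tables without values per library. The fixed design had named edgeR as the main test only for counts per library. The group means, however, allowed the whole reads of both libraries to be recovered, because the smallest values are single reads of each library and every mean is a sum of whole multiples of these steps. In the wild type group 2 summary rows had several solutions. Of the splits that fitted the library totals, the one with the smallest difference between libraries was taken. At least 99.9946% of gene values in each group lay within 0.01 of a whole number, and the recovered reads added up to each library's total. In 5 simulated sets of group means the method returned both counts of every gene (100% of 5000 genes). The libraries of a group carry no label in the tables, so they are called A (more reads) and B (fewer reads), and neither control library could be assigned to its genotype.

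The tests on recovered reads were chosen after the data had been seen. They were edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on all 8 libraries with 4 groups, TMM scaling and filterByExpr, which kept 13206 genes, and DESeq2 1.42.0. Summary rows stayed out of these tests and of their library sizes: reads outside annotated genes made up 33.9% to 39.0% of a library, reads without a unique alignment 26.3% to 36.3%, and reads on more than one gene 0.882% to 1.89%. Levels are counts per 1000000 TMM-scaled gene reads (CPM), given as mean ± SD over the 2 libraries of a group, and fitted log2 fold changes carry their SE. A fold against a group with no reads was computed against 3 reads over the group and is a lower bound, and with 1 to 3 reads a ratio with its exact 95% counting interval is given. Such intervals cover counting error only. On simulated counts for the activated and control groups (12533 genes), edgeR recovered 10% of genes changed 2-fold, 68% at 4-fold, 90% at 8-fold and 88% at 16-fold. For null against control (12566 genes) these shares were 4%, 60%, 76% and 88%, and for activated against null (12537 genes) 12%, 64%, 78% and 88%. Changes near 2-fold were therefore mostly below the reach of this test. Each fold had 50 changed genes. Unchanged genes called in these simulated comparisons numbered 4, 5 and 13 in that order. The 13 stood beside 6, 32, 39 and 44 genes recovered at 2-, 4-, 8- and 16-fold.

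Before the data were examined, 25 gene lists were fixed: Wnt feedback targets, the β-catenin destruction complex and TCF factors, pericentral and periportal hepatocyte genes, urea cycle and ammonia handling, gluconeogenesis, lipogenesis, fatty acid oxidation, bile acid, xenobiotic and cholesterol metabolism, cell cycle, hepatocyte transcription factors, fetal and progenitor genes, acute phase, clock genes, isolation stress, sex-biased genes, and markers of Kupffer cells, endothelium, stellate cells, cholangiocytes, lymphocytes, neutrophils and erythroid cells. Of the listed genes, 6 of the urea cycle list and 5 of the gluconeogenesis list also stand on the periportal list, and 7 of the xenobiotic list on the pericentral list. The sex-biased list mixes male-biased, female-biased and Y-linked genes and Xist, so a direction over this list does not measure sex bias. List members called higher or lower by the authors were tested with Fisher's exact test (two-sided) against all tested genes with a mean of at least 10 reads, with Benjamini-Hochberg adjustment over 50 tests per comparison. Fisher's exact test counts genes as independent units, so its p-values do not measure the spread between libraries. They are too small where list members move together. Camera, a competitive test of gene sets, was run on the recovered reads with a preset correlation of 0.01 and with an estimated one. For Kupffer cell markers in activated against control the estimated correlation was 0.974.

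The named genes followed a rule fixed before the data were examined: 14 genes in every comparison, the 6 higher and 6 lower genes with the largest fold among the authors' calls with a mean of at least 100 reads, and up to 4 members per list with the smallest adjusted p. In that rule a list could name more genes than the text has room for, so the text names 49 of 103 genes in activated against control, 42 of 103 in null against control, 39 of 103 in activated against null, 19 of 103 and 17 of 102 against wild type, and 27 of 106 in control against wild type. This subset was chosen after the values and their stability had been seen. Over all 6 comparisons, 40 fold changes of genes named by the rule turned direction under at least 1 alternative, and 9 of these stand in the text.

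The 5 chromatin lists were made with MACS, per the file headers without a control sample, at a p cutoff of 0.001, a tag size of 36 bp and an effective genome of 1.86e+09 bp. Each list gives, per the file headers, a tag count, a score (10 times the −log10 of the p-value) and a fold enrichment ratio over the library's own local background. These scores are the authors' own and served only to rank peaks within a list. Lists were compared by overlap of at least 1 bp, with exact binomial 95% intervals. The level of chance came from 100 circular shifts, along each chromosome, of the list whose peaks were counted. There was 1 library per list, so no test between conditions was possible. Planned analyses of peaks near regulated genes and of the TCF motif were not run, because no mm9 gene positions or sequence were used here. Alternatives comprised other thresholds, a fold minimum, the wild type as control, other scalings and filters, DESeq2, leaving out each library, stricter peak sets and peaks outside the input regions. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.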

Results

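Hepatocytes with β-catenin signalling switched on (Apc deleted) or off (Ctnnb1 deleted) were compared by mRNA sequencing and by chromatin immunoprecipitation of Tcf4, a DNA-binding partner of β-catenin encoded by Tcf7l2, and of β-catenin itself. In the liver lobule, hepatocytes around the central vein and around the portal vein carry out different metabolic tasks, and the series asks how Tcf4 and β-catenin occupancy relates to this zonation. The 4 mRNA groups (activated, null, control and wild type) held 2 libraries each. Libraries held 27887957 to 33142509 reads, except for wild type library A with 49868469. Reads on genes numbered 9006484 to 14374766. Libraries of one group correlated across genes at r = 0.94 (activated), 0.98 (null), 0.95 (control) and 0.97 (wild type) on the log2 scale. Genes are not independent replicates in such a correlation. Control library B correlated more with null library A and wild type library A (0.97 each) than with control library A.

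The deleted genes showed no called drop in whole-gene level. Ctnnb1 (ENSMUSG00000006932) averaged 226 ± 3.04 against 235 ± 18.4 CPM in null and control libraries (edgeR log2 fold change −0.06 ± 0.19, adjusted p = 1.00). Apc (ENSMUSG00000005871) averaged 55.2 ± 16.7 against 42.7 ± 1.70 CPM in activated and control libraries (edgeR log2 fold change 0.37 ± 0.23, adjusted p = 0.42). Counts over a whole gene include the exons that the deletion leaves in place, so these values check no label. Tcf7l2 averaged 21.1 ± 5.99 against 18.6 ± 7.70 CPM in activated and control libraries and 16.5 ± 0.137 CPM in null libraries. Neither edgeR nor the authors' deposited table called it against control. Of the 13 genes of the destruction complex and TCF list, the authors' deposited table called 3 higher and 0 lower in activated against control (4 higher adjusted over the list alone). In null against control it called 0 higher and 1 lower (1 lower adjusted over the list alone). By edgeR 0 of them were called in either comparison, also adjusted over the list alone.

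Activation of β-catenin against control raised Wnt feedback targets and pericentral genes and lowered periportal genes. Axin2 (ENSMUSG00000000142), a negative regulator of the pathway that the pathway itself induces, averaged 103 ± 1.66 against 3.65 ± 1.52 CPM (edgeR log2 fold change 4.81 ± 0.37, adjusted p = 0.00053). The stem cell receptor Lgr5 averaged 56.5 ± 13.8 against 2.10 ± 0.382 CPM (log2 fold change 4.75 ± 0.40, adjusted p = 0.0014). The receptor-degrading ligase Rnf43 rose by 3.52 ± 0.24 on the log2 scale (adjusted p = 0.00039) and the pathway inhibitor Nkd1 by 6.92 ± 0.82 (adjusted p = 0.0037). Of 13 measured Wnt feedback targets 12 rose and 0 fell in the authors' deposited table (Fisher's exact test, adjusted p = 6.58e-09; 12 adjusted over the list alone). By edgeR 11 were higher (12 adjusted over the list alone), and the list passed camera with adjusted p = 0.0177 with an estimated correlation.

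Among pericentral genes, Glul (ENSMUSG00000026473), the enzyme that makes glutamine from ammonia in the cells next to the central vein, averaged 9599 ± 43.7 against 346 ± 2.35 CPM (edgeR log2 fold change 4.79 ± 0.31, adjusted p = 0.00039). The amino acid transporter Slc1a4 averaged 83.2 ± 2.35 against 3.28 ± 0.232 CPM (edgeR adjusted p = 0.0012). The glutathione transferase Gstm3 averaged 392.3 ± 199 against 25.4 ± 5.42 CPM (edgeR adjusted p = 0.0013). Pericentral cytochrome P450 genes did not all pass the tests. Cyp2e1 averaged 6529.5 ± 2309.5 against 4465 ± 1569 CPM (edgeR adjusted p = 0.58), and Cyp1a2 1385 ± 309 against 505 ± 48.1 CPM (edgeR adjusted p = 0.058). The authors' deposited table gave adjusted p = 0.24 for Cyp2e1 and 3.3e-05 for Cyp1a2. The authors' deposited table had 24 of 31 pericentral genes higher and 0 lower (Fisher's exact test, adjusted p = 7.61e-14; 24 higher adjusted over the list alone). By edgeR 15 were higher (22 adjusted over the list alone), and camera gave adjusted p = 0.0264 with an estimated correlation. Glul and Oat can share reads with the gene models Glns-ps1 and Oat-rs1, the Gstm genes with one another, and Cyp4a12a with Cyp4a12b, so their levels are uncertain throughout.

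Periportal genes fell. Hal (ENSMUSG00000020017), which starts histidine breakdown, averaged 24.2 ± 4.40 against 635 ± 159 CPM (edgeR log2 fold change −4.71 ± 0.31, adjusted p = 0.00039). Gls2 (ENSMUSG00000044005), the liver glutaminase that releases ammonia, averaged 31.9 ± 5.65 against 574 ± 16.02 CPM (log2 fold change −4.17 ± 0.25, adjusted p = 0.00039). Cyp2f2 averaged 33.9 ± 5.26 against 1623 ± 389 CPM (log2 fold change −5.58 ± 0.39, adjusted p = 0.00045). Of 30 periportal genes 0 rose and 21 fell in the authors' deposited table (Fisher's exact test, adjusted p = 8.60e-30; 1 higher and 23 lower adjusted over the list alone). By edgeR 23 were lower (27 adjusted over the list alone), and camera gave adjusted p = 0.0177 with an estimated correlation. Of 14 urea cycle and ammonia genes 2 rose and 6 fell in the authors' deposited table (adjusted p = 3.63e-07 for lower; 3 and 6 adjusted over the list alone). By edgeR 0 were higher and 8 lower (1 and 9 adjusted over the list alone; camera adjusted p = 0.0268 with an estimated correlation). The urea cycle enzymes Cps1 (1360.1 ± 549 against 7033 ± 480.3 CPM), Ass1 (50.7 ± 2.68 against 279 ± 16.3 CPM) and Arg1 (98.2 ± 10.9 against 883 ± 22.0 CPM) fell by both tests, with edgeR adjusted p = 0.0052, 0.00053 and 0.00039.

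Some glucose and fat synthesis genes fell as well. Of 16 gluconeogenesis genes the authors' deposited table had 0 higher and 5 lower (Fisher's exact test, adjusted p = 2.21e-05; 7 lower adjusted over the list alone). By edgeR 9 were lower (13 adjusted over the list alone), but camera gave adjusted p = 0.0850 with an estimated correlation. Pck1, G6pc, Fbp1 and Sds, all on the path from amino acids or lactate to glucose, changed by −1.95 ± 0.37, −2.28 ± 0.35, −2.12 ± 0.23 and −4.72 ± 0.35 on the log2 scale (edgeR adjusted p = 0.025, 0.012, 0.0025 and 0.00048). Of 14 lipogenesis genes the authors' deposited table had 3 lower (adjusted p = 0.00589; 3 adjusted over the list alone). The edgeR fit had 3 lower too (5 adjusted over the list alone), with adjusted p = 0.0563 with an estimated correlation. Acly, which supplies acetyl-CoA for fat synthesis, averaged 153 ± 25.7 against 475 ± 40.7 CPM (edgeR adjusted p = 0.0097).

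**Figure D1:**
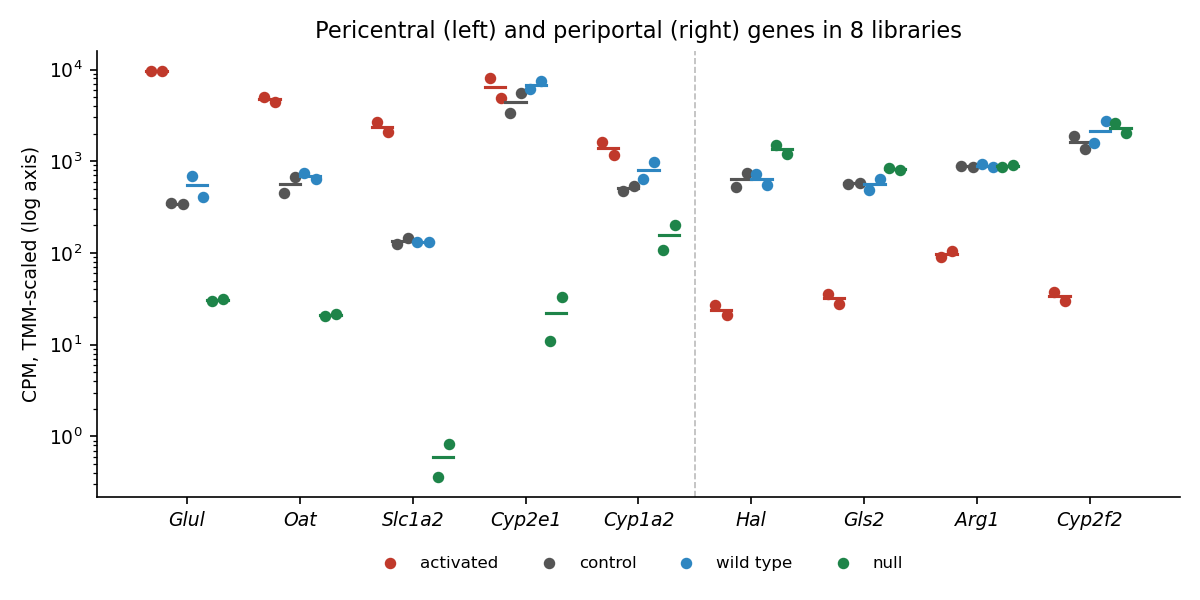
Each point is 1 library and each bar the mean of a group of 2, on a log axis in TMM-scaled CPM, for 5 pericentral genes (left of the dashed line) and 4 periportal genes (right). Glul averaged 9599 ± 43.7 CPM in activated and 30.8 ± 1.51 in null libraries, and Hal 24.2 ± 4.40 in activated and 1356 ± 210.2 in null libraries, with control and wild type in between for both genes.

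Drug, bile acid and cell cycle genes moved in activated hepatocytes with less support. Of 33 xenobiotic genes the authors' deposited table had 13 higher and 3 lower (adjusted p = 0.00134 and 0.0495; 14 and 4 adjusted over the list alone). By edgeR these were 8 and 3 (12 and 4 adjusted over the list alone), with adjusted p = 0.425 with an estimated correlation. Cyp2c55 averaged 53.4 ± 32.1 against 2.47 ± 0.453 CPM (edgeR adjusted p = 0.0029). Of 21 bile acid genes 7 were higher and 3 lower in the authors' deposited table (adjusted p = 0.0575 and 0.0169; 7 and 3 adjusted over the list alone). By edgeR 3 were higher and 4 lower (4 and 8 adjusted over the list alone), with adjusted p = 0.425 with an estimated correlation. Cyp8b1, which sets the share of cholic acid, averaged 7.26 ± 1.30 against 471 ± 236 CPM (edgeR log2 fold change −6.01 ± 0.43, adjusted p = 0.00045). The exporter Abcc4 averaged 22.9 ± 3.62 against 1.505 ± 0.913 CPM (adjusted p = 0.0074), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 392.3 ± 177 against 148 ± 96.2 CPM (adjusted p = 0.19). Of 29 cell cycle genes 20 were higher in the authors' deposited table (adjusted p = 2.92e-10; 20 adjusted over the list alone). The edgeR fit called 1, Ccnd1, a Wnt target that drives entry into S phase (735 ± 107 against 66.1 ± 29.7 CPM, adjusted p = 0.0092), and the list had adjusted p = 0.425 with an estimated correlation. The proliferation marker Mki67 averaged 59.2 ± 19.7 against 11.3 ± 14.4 CPM (edgeR adjusted p = 0.20) and Top2a 23.8 ± 7.96 against 4.95 ± 6.69 CPM (adjusted p = 0.27). Control library A held 21.5 CPM of Mki67 and control library B 1.18 CPM. Of 3 measured fetal and progenitor genes the authors' deposited table called 3 higher (adjusted p = 0.0107; 3 adjusted over the list alone). By edgeR 2 were higher, with adjusted p = 0.0871 with an estimated correlation. They included the fetal serum protein Afp (29.7 ± 10.1 against 3.06 ± 0.991 CPM, edgeR adjusted p = 0.0021) and Prom1, whose level was 63.8 (95% interval 17.4 to 531) times that in control by counted reads (adjusted p = 0.0097).

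The genes with the largest changes lay partly outside the lists. Elastin (Eln) had no read in control libraries and was at least 163-fold higher in activated libraries (edgeR adjusted p = 0.0026). The secreted Wnt target Ccn5 was at 416 (95% interval 142 to 2019.6) times the control level by counted reads, and the gene ENSMUSG00000091793, listed without a symbol, averaged 156 ± 131 against 1.13 ± 0.0772 CPM. The processed-type gene model Gm13857 was at 106 (95% interval 35.9 to 515) times the control level, which is uncertain because reads can be shared with a similar gene. The protease inhibitor Slpi averaged 47.9 ± 57.5 against 0.484 ± 0.0755 CPM (edgeR adjusted p = 0.027), with 7.31 and 88.6 CPM in the activated libraries. The carboxylesterase Ces3b fell to 6.39 ± 3.30 against 310.5 ± 11.1 CPM (edgeR adjusted p = 0.00046), and the gene model Gm15883 to 6.92 ± 0.559 against 323 ± 54.3 CPM (adjusted p = 0.00039). The male-biased genes Cyp4a12a (0.594 ± 0.716 against 140.4 ± 168 CPM, edgeR adjusted p = 0.021) and Elovl3 (1.59 ± 1.24 against 63.3 ± 84.2 CPM, adjusted p = 0.083) differed between libraries of one group. They stood at 21.6 and 259 CPM and at 3.76 and 123 CPM in the control libraries. Over 16 sex-biased genes, male-biased and female-biased together, the authors' deposited table had 2 higher and 6 lower (adjusted p = 8.23e-07 for lower; 3 and 6 adjusted over the list alone). By edgeR these were 0 and 3 (0 and 6 adjusted over the list alone), with adjusted p = 0.509 with an estimated correlation.

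Markers of other liver cells were also higher in the authors' deposited table. These were 14 of 14 Kupffer cell markers (Fisher's exact test, adjusted p = 1.89e-11; 14 adjusted over the list alone), 12 of 15 endothelial markers (1.46e-07; 15 adjusted over the list alone) and 9 of 11 stellate markers (4.95e-06; 10 adjusted over the list alone). By edgeR after its filter 0 were called in these 3 lists, also adjusted over the list alone. Without the filter edgeR called Marco (log2 fold change 2.65, adjusted p = 0.0031) and did not call Cd5l (adjusted p = 0.11). Their adjusted p was 0.602, 0.509 and 0.541 with an estimated correlation. The Kupffer receptor Marco reached 9.59 and 178 CPM in the activated libraries and 26.3 and 3.76 CPM in the control libraries. Cd5l stood at 59.99, 464, 159.6 and 16.5 CPM. Without activated library B the edgeR log2 fold change of Marco was −0.62 and that of Cd5l −0.53. The endothelial genes Stab1 (56.3 ± 26.8 against 16.5 ± 17.0 CPM) and Kdr (26.7 ± 1.44 against 7.15 ± 8.59 CPM) and the stellate gene Reln (24.1 ± 5.17 against 7.04 ± 3.12 CPM) had edgeR adjusted p = 0.29, 0.39 and 0.18. Control library A held more of these markers and of the cell cycle genes than control library B. The median Kupffer marker stood at 32.3 and 3.65 CPM, the median endothelial marker at 11.9 and 1.72 CPM, and the median cell cycle gene at 7.42 and 1.72 CPM.

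The remaining lists showed few or conflicting calls. Of 18 acute phase genes 5 were higher in the authors' deposited table (adjusted p = 0.387; 5 higher and 3 lower adjusted over the list alone), but edgeR with TMM scaling had 0 higher and 5 lower (1 and 5 adjusted over the list alone; adjusted p = 0.602 with an estimated correlation). Lcn2 averaged 554 ± 665 against 143 ± 20.6 CPM (edgeR adjusted p = 0.49) and turned to a log2 fold change of −0.74 without activated library B. Of 14 isolation stress genes 5 were higher in the authors' deposited table (adjusted p = 0.0961; 5 higher and 1 lower adjusted over the list alone). By edgeR 1 was higher, Atf3 (14.7 ± 7.41 against 1.07 ± 0.609 CPM, adjusted p = 0.010). Of 23 fatty acid oxidation genes 2 were higher in the authors' deposited table. By edgeR 1 was higher, the pyruvate dehydrogenase kinase Pdk4 (21.7 ± 2.98 against 2.63 ± 0.535 CPM, adjusted p = 0.011). Clock genes (2 of 16 higher), cholesterol synthesis (1 of 18 higher), hepatocyte transcription factors (1 of 14 higher), lymphocyte markers (1 of 3 higher; 2 adjusted over the list alone) and cholangiocyte markers (0 of 5) had adjusted p of 0.794 or more for higher calls in the authors' deposited table. By edgeR 0 were called in each of these 5. The other marker lists had 1 measured gene each: the neutrophil gene was not called (1 higher adjusted over the list alone), and the erythroid gene was lower and not called by edgeR. Over 1 gene Fisher's exact test (adjusted p = 0.0495 for lower) reflects only the share of genes called lower.

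Over all genes the authors' deposited table called 1896 higher and 218 lower in activated against control (89.7% higher). With TMM scaling edgeR called 303 higher and 343 lower (46.9% higher) and DESeq2 448 and 595. Of these, 303 higher and 152 lower genes were called by both the authors and edgeR. The median log2 fold change was 0.53 on the authors' scale (genes with at least 10 reads) and 0.03 with TMM (the 13206 genes of the edgeR fit). Fitted values given here are therefore relative to that shift. The edgeR total of 646 became 249 without control library B.

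**Figure D2:**
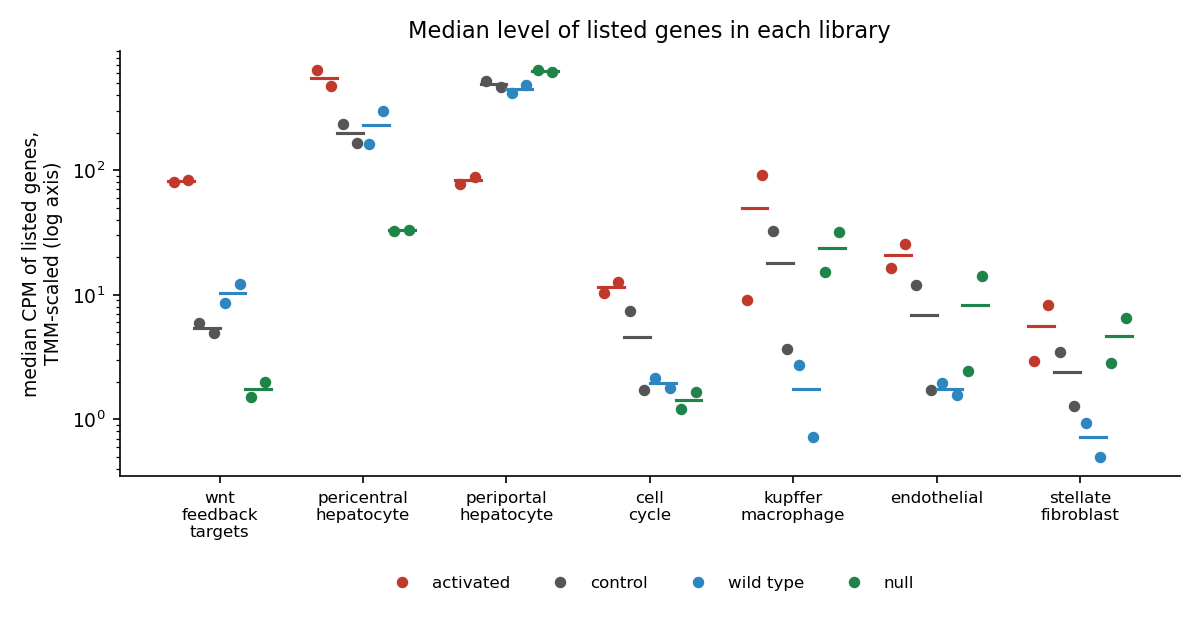
Each point is the median TMM-scaled CPM of the listed genes in 1 library, on a log axis, and each bar the mean of a group of 2. Pericentral genes were highest in both activated libraries (636 and 470.3 CPM) and lowest in both null libraries (32.6 and 33.1 CPM), and Kupffer markers ranged from 9.002 to 91.2 CPM within the activated group.

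Loss of β-catenin against control lowered pericentral genes, some of them to a few reads. Cyp2e1 (ENSMUSG00000025479), which oxidises ethanol and paracetamol, averaged 22.0 ± 15.7 against 4465 ± 1569 CPM (edgeR log2 fold change −7.66 ± 0.66, adjusted p = 0.0033). Glul averaged 30.8 ± 1.51 against 346 ± 2.35 CPM (log2 fold change −3.49 ± 0.29, adjusted p = 0.0030), and the glutamate transporter Slc1a2 0.595 ± 0.325 against 135 ± 14.9 CPM (log2 fold change −7.79 ± 0.38, adjusted p = 0.00032). The ornithine aminotransferase Oat averaged 21.1 ± 0.966 against 563 ± 164 CPM (log2 fold change −4.74 ± 0.29, adjusted p = 0.00050). Of 31 pericentral genes 0 rose and 24 fell in the authors' deposited table (Fisher's exact test, adjusted p = 1.79e-31; 26 lower adjusted over the list alone). By edgeR 10 were lower (23 adjusted over the list alone), and camera gave adjusted p = 0.00824 with an estimated correlation. Lect2 changed by −6.74 ± 0.38 on the log2 scale in the edgeR fit (adjusted p = 0.00041), Rdh9 by −6.10 ± 0.41 (adjusted p = 0.00076) and Cyp2a5 by −6.75 ± 0.81 (adjusted p = 0.024). The dicarboxylate transporter Slc13a3 was at 0.00177 (95% interval 4.48e-05 to 0.00991) times the control level by counted reads.

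Wnt feedback targets fell as well. Axin2 had 1 read over both null libraries, 0.0164 (95% interval 4.09e-04 to 0.0944) times the control level (edgeR adjusted p = 0.038). Lgr5 had none, at least 11.7-fold lower (edgeR adjusted p = 0.13; called in the authors' deposited table). Of 8 measured targets 5 fell in the authors' deposited table (adjusted p = 4.93e-06; 7 adjusted over the list alone). By edgeR 1 was lower (4 adjusted over the list alone), and camera gave adjusted p = 0.0218 with an estimated correlation. Tbx3 (1.31 ± 0.987 against 13.4 ± 5.99 CPM) and Notum (10.9 ± 2.47 against 31.8 ± 6.57 CPM) were lower in the authors' deposited table and were not called by edgeR after its filter (adjusted p = 0.13 and 0.49). Neither was Myc, lower in the same table, which reached 65.0 and 5.15 CPM in the control libraries and whose log2 fold change turned to 1.13 without control library A.

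Few periportal genes of null hepatocytes were called against control. Hal averaged 1356 ± 210.2 against 635 ± 159 CPM (edgeR adjusted p = 0.54; adjusted p = 0.0026 in the authors' deposited table). Arg1 averaged 882 ± 28.6 against 883 ± 22.0 CPM, Cps1 7846 ± 327 against 7033 ± 480.3 CPM, Gls2 830.4 ± 30.1 against 574 ± 16.02 CPM, Pck1 4586 ± 310.1 against 5634 ± 464 CPM and Cyp2f2 2308 ± 409.7 against 1623 ± 389 CPM, and neither test called these 5. Of 30 periportal genes 3 rose in the authors' deposited table, Cdh1 and Gldc among them (adjusted p = 0.00416; 6 adjusted over the list alone). By edgeR 0 were called, also adjusted over the list alone, and the list had adjusted p = 0.239 with an estimated correlation. Urea cycle (0 higher, 1 lower of 14), gluconeogenesis (0 and 1 of 16) and cholesterol synthesis genes (0 and 1 of 18) had adjusted p of 0.758 or more in the authors' deposited table (1, 3 and 1 lower adjusted over the list alone), and 0 edgeR calls. The lower urea cycle list gene was the glycerol channel Aqp9 (199.9 ± 23.2 against 374 ± 39.1 CPM, edgeR adjusted p = 0.50).

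Several other groups had genes that were lower in the authors' deposited table. Of 31 xenobiotic genes 3 were higher and 12 lower there (Fisher's exact test, adjusted p = 0.00416 and 7.64e-11; 4 and 18 adjusted over the list alone). By edgeR 3 were lower (1 higher and 8 lower adjusted over the list alone), with adjusted p = 0.119 with an estimated correlation, among them Gstm2 (2.68 ± 1.38 against 33.3 ± 0.492 CPM) and Gstm3 (2.27 ± 0.118 against 25.4 ± 5.42 CPM). The barbiturate-induced Cyp2b10, one of the higher genes, averaged 134 ± 26.6 against 17.5 ± 12.2 CPM (edgeR adjusted p = 0.14). In the authors' deposited table, cell cycle genes had 1 of 26 higher and 12 lower (adjusted p = 8.78e-12 for lower; 1 and 15 adjusted over the list alone), whereas null against wild type had 1 of 17 higher and 0 lower. In null against control, clock genes had 2 of 17 higher and 9 lower (8.79e-10 for lower; 2 and 12 adjusted over the list alone), and 1 and 11 in null against wild type. Fatty acid oxidation had 0 of 23 higher and 7 lower (8.27e-06; 9 lower adjusted over the list alone). Bile acid genes had 0 of 20 higher and 6 lower (4.17e-05; 7 lower adjusted over the list alone). Sex-biased genes had 2 of 16 higher and 6 lower (1.07e-05 for lower; 2 and 9 adjusted over the list alone). Lipogenesis genes had 0 of 14 higher and 3 lower (0.0161; 3 and 3 adjusted over the list alone). By edgeR 0 were called in these 6 lists, and their adjusted p was 0.341 or more with an estimated correlation. Control libraries differed from each other in these genes. Mki67 stood at 21.5 and 1.18 CPM in the control libraries, the clock output gene Dbp at 113 and 24.2 CPM, Mcm6 at 19.8 and 3.33 CPM and Cyp4a14 at 57.6 and 904 CPM. The log2 fold change of Cyp4a14 turned to 0.84 without control library B. Cyp7a1 averaged 32.7 ± 14.0 against 148 ± 96.2 CPM and Thrsp 220.3 ± 27.7 against 511 ± 374 CPM (edgeR adjusted p = 0.54 and 1.00).

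The genes named for their rises in the authors' deposited table were Cyp2b10, the estrogen receptor Esr1, the hepcidin gene Hamp2, the phosphate transporter Slc34a2, the clock gene Arntl and the female-biased Cyp2b9. None of these 6 was called by edgeR. Esr1 was at 173 ± 8.62 against 31.1 ± 17.4 CPM (adjusted p = 0.28), Slc34a2 at 113 ± 35.5 against 25.5 ± 16.3 CPM (0.56). Cyp2b9 was at 224 ± 9.42 against 59.9 ± 73.6 CPM (1.00) and Hamp2 at 53.2 ± 41.3 against 10.8 ± 13.9 CPM (1.00). Stellate markers (2 of 9 higher in the authors' deposited table, adjusted p = 0.00561; 4 adjusted over the list alone) had 0 edgeR calls and adjusted p = 0.641 with an estimated correlation. Kupffer (0 of 14), endothelial (0 of 15), cholangiocyte (0 of 5), lymphocyte (0 of 2), erythroid (0 of 1), fetal (0 of 2) and hepatocyte transcription factor genes (0 of 13) had no call by either test. Acute phase genes had 1 higher and 1 lower of 17 in the authors' deposited table (6 and 1 adjusted over the list alone). Isolation stress genes had 1 lower of 10 (2 adjusted over the list alone), and no neutrophil gene had enough reads. Over all genes the authors' deposited table called 73 higher and 324 lower in null against control. With edgeR these were 0 and 22, all 22 of them also lower in the authors' deposited table, and with DESeq2 12 and 72. In the edgeR fit 599 genes had an unadjusted p below 0.05. Its 22 calls became 9 without null library A or without null library B.

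Between the opposite states, activated against null, pericentral genes and Wnt targets were higher and periportal genes lower. Slc1a2 averaged 2374 ± 429.6 against 0.595 ± 0.325 CPM (edgeR log2 fold change 11.93 ± 0.42, adjusted p = 1.3e-05) and Glul 9599 ± 43.7 against 30.8 ± 1.51 CPM (log2 fold change 8.29 ± 0.36, adjusted p = 1.9e-05). Cyp2e1 averaged 6529.5 ± 2309.5 against 22.0 ± 15.7 CPM (log2 fold change 8.21 ± 0.68, adjusted p = 0.00042), Oat 4744 ± 404 against 21.1 ± 0.966 CPM (log2 fold change 7.81 ± 0.34, adjusted p = 1.9e-05) and Cyp2a5 1126 ± 84.7 against 2.89 ± 1.25 CPM (log2 fold change 8.60 ± 0.87, adjusted p = 0.0011). Lgr5 was at least 318-fold higher and Axin2 at 1715 (95% interval 307 to 67752) times the null level by counted reads. The authors' deposited table had 30 of 31 pericentral genes higher and 1 lower (Fisher's exact test, adjusted p = 2.51e-10; 30 and 1 adjusted over the list alone) and 13 of 13 Wnt targets higher (3.44e-05; 13 adjusted over the list alone). By edgeR 26 pericentral genes were higher and 0 lower (27 and 1 adjusted over the list alone). Of the Wnt targets 11 were higher (12 adjusted over the list alone), and both lists had adjusted p = 0.0139 with an estimated correlation.

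Of 30 periportal genes 1 was higher and 26 lower in the authors' deposited table (Fisher's exact test, adjusted p = 7.85e-05 for a shortage of higher calls and 1.38e-32 for lower; 1 and 26 adjusted over the list alone). By edgeR 25 were lower (28 adjusted over the list alone; adjusted p = 0.0139 with an estimated correlation). Hal averaged 24.2 ± 4.40 against 1356 ± 210.2 CPM (edgeR log2 fold change −5.81 ± 0.33, adjusted p = 7.8e-05) and Cyp2f2 33.9 ± 5.26 against 2308 ± 409.7 CPM (log2 fold change −6.09 ± 0.40, adjusted p = 0.00015). Of 14 urea cycle genes 3 were higher and 7 lower in the authors' deposited table (adjusted p = 2.43e-06 for lower; 4 and 7 adjusted over the list alone). Gluconeogenesis had 2 of 16 higher and 7 lower (6.09e-06; 2 and 7), and lipogenesis 2 of 15 higher and 5 lower (0.000527; 2 and 5). These 3 lists had adjusted p = 0.0585, 0.150 and 0.0704 with an estimated correlation. By edgeR 1 and 7, 0 and 10, and 0 and 5 of their genes were higher and lower, among them the desaturase Scd1 (1455 ± 614 against 8489.9 ± 506 CPM) and Acly (153 ± 25.7 against 605 ± 87.2 CPM). Of 29 cell cycle genes 27 were higher and 1 lower in the authors' deposited table (adjusted p = 2.34e-08; 27 and 1 adjusted over the list alone). By edgeR 15 were higher (22 adjusted over the list alone), which included Mki67 (59.2 ± 19.7 against 0.658 ± 0.0699 CPM, adjusted p = 0.015), Top2a (23.8 ± 7.96 against 0.534 ± 0.411 CPM, 0.037) and Ccnd1 (735 ± 107 against 29.8 ± 20.1 CPM, 0.0020). The list had adjusted p = 0.379 with an estimated correlation.

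Of 33 xenobiotic genes 23 were higher and 5 lower in the authors' deposited table (adjusted p = 0.00171 and 0.0196; 24 and 6 adjusted over the list alone). By edgeR 14 were higher and 4 lower (16 and 5 adjusted over the list alone; adjusted p = 0.159 with an estimated correlation). Bile acid genes (9 higher and 6 lower of 21, adjusted p = 0.000343 for lower), acute phase genes (5 and 5 of 19, 0.00167 for lower) and sex-biased genes (6 and 5 of 15, 0.000527 for lower) passed the Fisher test in the authors' deposited table (9 and 6, 5 and 5, and 7 and 5 adjusted over the list alone). By edgeR 6 and 3, 1 and 5, and 0 and 1 of them were called, with adjusted p = 0.625 for each with an estimated correlation. Kupffer (14 of 14 higher) and endothelial markers (14 of 15 higher) passed it too (adjusted p = 1.56e-05 and 9.95e-05 in the authors' deposited table; 14 and 15 adjusted over the list alone). They had 0 edgeR calls after its filter and adjusted p = 0.835 and 0.625 with an estimated correlation. Without the filter edgeR called Cd5l (log2 fold change 2.10, adjusted p = 0.016). Cd5l stood at 59.99 and 464 CPM in the activated and 40.8 and 82.1 CPM in the null libraries. It turned to a log2 fold change of −0.0125 without activated library B. The clock genes Dbp (76.8 ± 8.83 against 2.88 ± 0.0645 CPM, edgeR adjusted p = 0.064) and Per2 (49.4 ± 7.36 against 7.66 ± 0.167 CPM, 0.038) belong to a list with 11 of 17 higher and 3 lower in the authors' deposited table (adjusted p = 0.115 and 0.0661). Genes without a read in the null libraries included Gm13872 (at least 582-fold higher, uncertain because reads can be shared with a similar gene), ENSMUSG00000091793 (at least 896-fold), Nptx1 (at least 152-fold) and Eln (at least 146-fold). Hamp2 (0.162 ± 0.104 against 53.2 ± 41.3 CPM) and Cyp4a12a (0.594 ± 0.716 against 147 ± 0.685 CPM) were among the genes lower by the most in the authors' deposited table.

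Ctnnb1 passed in the authors' deposited table (adjusted p = 0.016) but averaged 228 ± 36.1 against 226 ± 3.04 CPM with TMM scaling. Its log2 fold change ranged from −0.18 to 0.19 when 1 library was left out. Over all genes the authors' deposited table called 5431 higher and 477 lower in activated against null (91.9% higher). With TMM scaling these were 687 and 674 (50.5% higher) by edgeR, and 819 and 826 by DESeq2. The median log2 fold change was 0.63 on the authors' scale (genes with at least 10 reads) and 0.03 with TMM (genes of the edgeR fit). Of the genes higher in the authors' deposited table, 106 had a negative edgeR value. The edgeR total of 1361 became 376 without null library A, 402 without null library B and 786 without activated library A.

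Opposite regulation by the 2 mutants was counted over 18458 genes tested against control in both of the authors' deposited tables. There, 146 genes were higher in activated and lower in null hepatocytes, against 32.6 for independent lists, and 11 were lower in activated and higher in null, against 0.862. Genes moving the same way numbered 20 higher (7.35 for independent lists) and 25 lower (3.83). edgeR called 18 genes higher in activated and lower in null, against 0.505 for independent lists, and 0 the other way (0 lower in both). Chosen after their values were seen, Glul, Axin2, Slc1a2, Oat, Lect2, Rdh9, Slc13a3, Gstm2 and Gstm3 were among these 18. With wild type in place of control (18370 genes), the authors' deposited tables had 158 genes higher in activated and lower in null (92.5 for independent lists) and 16 the other way (10.1). More genes moved the same way there, 482 higher in both mutants (112) and 71 lower in both (8.31). edgeR then had 27 genes higher in activated and lower in null (2.96), 1 the other way (1.38), 22 higher in both (2.02) and 2 lower in both (2.02). In 20 simulations by edgeR of unchanged groups against shared controls, means of 2.4 opposite and 136.5 same-direction genes passed an unadjusted p below 0.05 in both comparisons. At an adjusted p below 0.05, which few unchanged genes can pass, the means were 0 and 0.1. With a separate control library for each mutant, edgeR called 12 and 26 genes in opposite directions (by which library went with which mutant) and 0 and 0 in the same direction. With a separate wild type library for each mutant these were 23 and 19 in opposite directions and 3 and 2 in the same direction, against 28 and 24 with both libraries shared.

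Against uninjected wild type, genes of the same zonation lists moved. In activated libraries Axin2 averaged 103 ± 1.66 against 7.91 ± 2.37 CPM (edgeR log2 fold change 3.68 ± 0.34, adjusted p = 0.0010) and Glul 9599 ± 43.7 against 549 ± 194 CPM (log2 fold change 4.13 ± 0.30, adjusted p = 0.00044). Hal averaged 24.2 ± 4.40 against 638 ± 118 CPM (log2 fold change −4.72 ± 0.31, adjusted p = 0.00039). The authors' deposited table had 22 of 31 pericentral genes and 13 of 13 Wnt targets higher (Fisher's exact test, adjusted p = 4.74e-08 and 2.75e-08) and 19 of 30 periportal genes lower (6.04e-23). These 3 lists had adjusted p = 0.0482, 0.0287 and 0.0288 with an estimated correlation. There, 26 of 29 cell cycle genes were higher (adjusted p = 2.11e-13; adjusted p = 0.398 with an estimated correlation). Adjusted over the list alone these were 22, 13, 20 and 28, and edgeR called 16, 12, 24 and 20. Mki67 was at 733 (95% interval 203 to 6057) times the wild type level by counted reads, Ccnd1 averaged 735 ± 107 against 18.2 ± 1.70 CPM, and Cenpf, a centromere protein gene without a read in wild type, was at least 118-fold higher. Elovl3 (1.59 ± 1.24 against 266 ± 119.9 CPM), Selenbp2 (8.07 ± 1.94 against 855 ± 519 CPM), Cyp4a12b (0.216 ± 0.194 against 57.8 ± 47.1 CPM) and Mup21 (0.403 ± 0.320 against 35.6 ± 28.5 CPM) fell by both tests. Kupffer markers were higher for 14 of 14 genes in the authors' deposited table and 5 by edgeR (14 adjusted over the list alone), with adjusted p = 0.536 with an estimated correlation. Endothelial markers were higher for 14 of 15 genes in that table and 5 by edgeR (13 adjusted over the list alone), and stellate markers for 11 of 12 and 2 by edgeR (9), both with adjusted p = 0.515 with an estimated correlation. Over all genes the authors' deposited table called 3480 higher and 303 lower (92.0% higher). With edgeR these were 952 and 652 (59.4% higher), and with DESeq2 1352 and 845. The edgeR total of 1604 became 362 without wild type library B and 500 without wild type library A.

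In null against wild type libraries Cyp2e1 averaged 22.0 ± 15.7 against 6836 ± 970.3 CPM (edgeR log2 fold change −8.27 ± 0.68, adjusted p = 0.0018) and Glul 30.8 ± 1.51 against 549 ± 194 CPM (log2 fold change −4.16 ± 0.30, adjusted p = 0.00095). Slc1a2 averaged 0.595 ± 0.325 against 132 ± 0.824 CPM (log2 fold change −7.75 ± 0.37, adjusted p = 0.00020) and Rdh9 0.601 ± 0.183 against 80.9 ± 24.5 CPM (log2 fold change −7.05 ± 0.41, adjusted p = 0.00028). Lgr5 was at least 35.6-fold lower and Axin2 at 0.00717 (95% interval 1.81e-04 to 0.0404) times the wild type level. Of 31 pericentral genes 26, and of 10 Wnt targets 7, were lower in the authors' deposited table (Fisher's exact test, adjusted p = 3.38e-30 and 1.42e-07; 28 and 7 adjusted over the list alone). By edgeR these were 14 and 5, with adjusted p = 0.0139 and 0.0454 with an estimated correlation. Slc34a2 (113 ± 35.5 against 0.815 ± 0.680 CPM), Cyp2b10 (134 ± 26.6 against 2.34 ± 1.27 CPM) and the transporter Slc22a26 (24.5 ± 6.14 against 0.315 ± 0.288 CPM) rose by both tests (edgeR adjusted p = 0.0073, 0.0067 and 0.0067). So did the early response gene Egr1 (92.7 ± 39.2 against 16.7 ± 1.22 CPM, adjusted p = 0.029). The male-biased Hsd3b5 fell (0.956 ± 0.148 against 219 ± 27.1 CPM, adjusted p = 0.020). Kupffer markers were higher for 14 of 14 genes in the authors' deposited table (adjusted p = 3.03e-19) and 0 by edgeR (0.479 with an estimated correlation). Clock genes there had 1 of 17 higher and 11 lower (adjusted p = 5.34e-11 for lower; 2 and 11 adjusted over the list alone), with 0 edgeR calls and adjusted p = 0.349 with an estimated correlation. Xenobiotic genes had 4 of 31 higher and 16 lower in the authors' deposited table (1.46e-13 for lower; 4 and 18 adjusted over the list alone), and 1 higher and 4 lower by edgeR (0.249 with an estimated correlation). Over all genes the authors' deposited table called 613 higher and 504 lower (54.9% higher). With edgeR these were 28 and 41 (40.6% higher), and with DESeq2 157 and 134. The 69 edgeR calls became 16 without null library A, 17 without null library B, 36 without wild type library A and 38 without wild type library B.

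Tamoxifen-injected control libraries without Cre and uninjected wild type libraries differed in genes of other cell types, stress and sex-biased metabolism in the authors' deposited table. There, 14 of 14 Kupffer markers (Fisher's exact test, adjusted p = 5.27e-21), 12 of 26 cell cycle genes (2.56e-11), and 7 of 13 endothelial markers (2.68e-07) were higher in control. So were 4 of 11 isolation stress genes (0.00153), 3 of 7 stellate markers (0.00533) and 4 of 23 fatty acid oxidation genes (0.0226). Of 15 sex-biased genes 3 were higher and 4 lower (0.0392 and 8.60e-06), and the 1 measured erythroid gene, Alas2, was lower (0.0298, which over 1 gene reflects only the share of genes called lower). Adjusted over the list alone these were 14, 13, 12, 8, 5 and 4 higher, 4 and 5, and 1 lower. With an estimated correlation the adjusted p of these lists was 0.531 or more, except for the erythroid gene, whose list had too few genes for that test. By edgeR after its filter 0 genes of all these lists were called. The median cell cycle gene stood at 7.42 and 1.72 CPM in control libraries A and B and at 2.14 and 1.78 CPM in wild type libraries. For endothelial markers these were 11.9 and 1.72 against 1.94 and 1.56 CPM, and for Kupffer markers 32.3 and 3.65 against 2.75 and 0.724 CPM. In the first 2 of these lists control library B lay near wild type, so the difference lay mainly in control library A. The zonation genes Glul (346 ± 2.35 against 549 ± 194 CPM), Cyp2e1 (4465 ± 1569 against 6836 ± 970.3 CPM), Hal (635 ± 159 against 638 ± 118 CPM) and Gls2 (574 ± 16.02 against 568 ± 111 CPM) and the Wnt targets Axin2 (3.65 ± 1.52 against 7.91 ± 2.37 CPM) and Lgr5 (2.10 ± 0.382 against 5.92 ± 2.54 CPM) were called by neither test. Rnf43 (13.0 ± 2.60 against 33.2 ± 4.40 CPM) was lower in the authors' deposited table and was not called by edgeR after its filter (adjusted p = 0.22).

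The female-biased Cyp2a4 averaged 20.96 ± 6.10 against 0.385 ± 0.0859 CPM and Cyp2b9 59.9 ± 73.6 against 0.153 ± 0.0587 CPM in control and wild type. Slc34a2 averaged 25.5 ± 16.3 against 0.815 ± 0.680 CPM, Egr1 88.2 ± 23.3 against 16.7 ± 1.22 CPM, and Hsd3b5 20.2 ± 12.9 against 219 ± 27.1 CPM (edgeR adjusted p = 0.24, 0.55, 0.12, 0.15 and 0.45). All 5 were called in the authors' deposited table. Cyp26a1, a retinoic acid hydroxylase, stood at 184 and 13.5 CPM in the wild type libraries. Its log2 fold change of −2.41 in the authors' deposited table turned to 0.56 by edgeR without wild type library A. Stab1 turned to −0.0835 without control library A. Over all genes the authors' deposited table called 417 higher and 63 lower, and DESeq2 89 and 17. By edgeR after its filter 0 were called, with 934 genes at an unadjusted p below 0.05, and 47 (46 higher and 1 lower) without control library B. Without the filter edgeR called 382 (335 higher and 47 lower).

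Tcf4 and β-catenin occupancy was compared as lists of regions called by the authors (build mm9). Activated hepatocytes gave 49769 Tcf4 peaks and 40726 β-catenin peaks, and null hepatocytes 43018 Tcf4 peaks. The sonicated input chromatin without antibody gave 46105 (activated) and 23834 (null) regions. Chromatin libraries held 5733498 to 8052946 tags, of which 76.97% to 80.9% were unique, except for the null input with 48.9%. Peaks had median lengths of 510.0 to 572 bp in the antibody libraries. Tags in peaks made up 22.4% of unique tags for activated Tcf4, 12.4% for null Tcf4 and 8.81% for β-catenin, beside 13.8% and 9.04% for the activated and null input.

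Of the activated Tcf4 peaks 38.7% (exact binomial 95% interval 38.3% to 39.2%) overlapped a null Tcf4 peak, against 2.48% after circular shifts. Of null Tcf4 peaks 44.7% (44.3% to 45.2%) overlapped an activated one. Of β-catenin peaks 39.0% (38.6% to 39.5%) overlapped an activated Tcf4 peak, against 2.69% after shifts, and 30.5% (30.0% to 30.9%) a null Tcf4 peak. Many of these regions were also called in input. In all, 33.6% of activated Tcf4, 26.5% of β-catenin and 22.0% of null Tcf4 peaks overlapped an input region of the same genotype, against 2.51%, 2.34% and 1.21% after shifts. The 2 input lists, made without antibody, overlapped each other as well. Of activated input regions 22.3% overlapped a null one, and of null input regions 43.9% an activated one, against 1.14% and 2.22% after shifts. An excess over shifts therefore does not by itself show shared occupancy by the factors. Outside input regions of either genotype, 23.7% of activated Tcf4 peaks overlapped a null Tcf4 peak and 18.7% of β-catenin peaks an activated Tcf4 peak, against 1.33% and 1.30% after shifts.

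The share of peaks overlapping another list changed with the authors' score. Of the 1000 β-catenin peaks with the highest authors' scores, 222 lay outside both input lists. Of these 92.8% overlapped an activated Tcf4 peak and 55.0% a null Tcf4 peak. Among the 1000 highest activated Tcf4 peaks 137 lay outside the input lists, of which 95.6% overlapped a β-catenin peak and 51.8% a null Tcf4 peak. In the lowest band of scores these shares were 14.0% and 11.7% for β-catenin peaks and 12.3% and 18.0% for activated Tcf4 peaks. Outside the input lists the share of activated Tcf4 peaks overlapping a null Tcf4 peak was highest below the top band, at 59.8% for ranks 1001 to 5000 and 58.3% for ranks 5001 to 10000. Over all activated Tcf4 peaks it was highest in the top band (86.2%) and lowest in the last (22.0%). Of 18869 pairs of Tcf4 peaks that overlapped one to one, the activated peak had the higher density of tags (per unique tag and base) by a median of 0.52 on the log2 scale (5th to 95th percentile −0.37 to 1.63), and by 0.32 in the 7022 pairs outside the input lists. With 1 library per condition this compares libraries, not conditions.

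**Figure D3:**
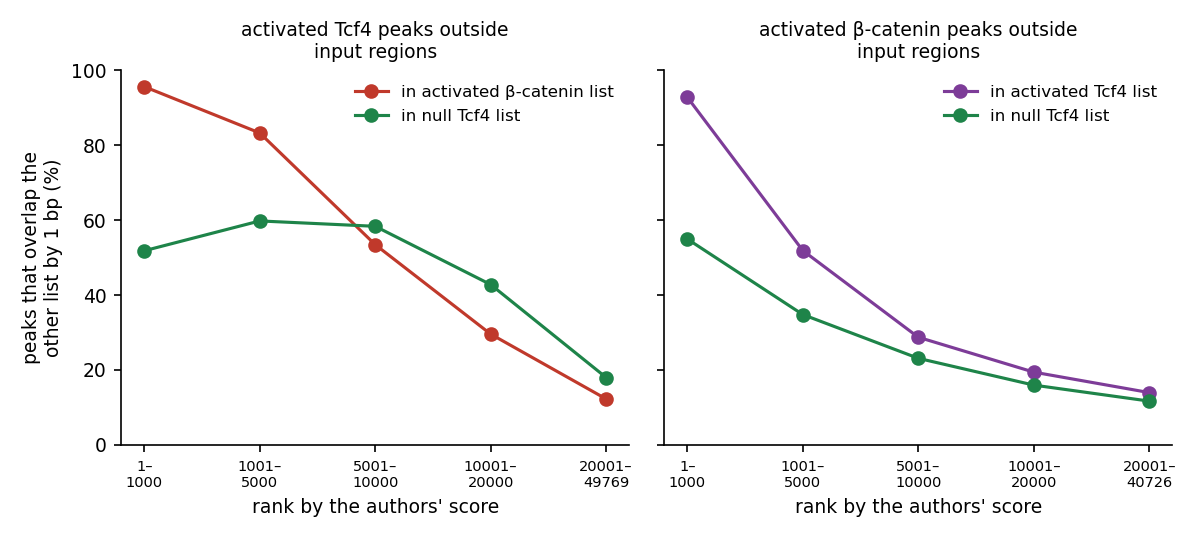
Each point is the percentage of peaks outside the input regions that overlap another list by at least 1 bp, in bands of rank by the authors' score within each list, for activated Tcf4 (left) and β-catenin peaks (right). Among the 1000 highest-scored β-catenin peaks 92.8% lay in the activated Tcf4 list, and in the lowest band 14.0%.

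The 5 highest-scored peaks of each antibody list all overlapped an input region. The highest β-catenin peak lay on chromosome 16 from 30064087 to 30065606 (834 tags, fold enrichment 10.2) and the highest activated Tcf4 peak on chromosome 12 from 15756247 to 15757144 (273 tags, fold enrichment 17.8). The highest null Tcf4 peak, on chromosome 9 from 35112659 to 35113218, overlapped the top region of both input lists. Outside the input regions, the highest activated Tcf4 peak lay on chromosome 6 from 51670541 to 51671185 and overlapped a peak in the β-catenin and null Tcf4 lists. The highest such β-catenin peak lay on chromosome 16 from 35005457 to 35005912 and overlapped an activated but no null Tcf4 peak. The highest such null Tcf4 peak lay on chromosome 5 from 136170440 to 136171720 and overlapped peaks of both other antibody lists. Genes at these positions were not looked up, because no mm9 annotation was used here.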

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

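Of the tests in this part, the scaling by reads on genes and the look for a spiked-in reference were chosen after the result was seen, and the scaling without the 50 most abundant genes was set before its result was seen. Reads outside annotated genes, part of the authors' library totals but not of the gene counts above, made up 37.7% and 39.0% of the activated libraries and 36.5% and 36.8% of the null libraries, above the 35.8% to 36.4% of the control libraries. The authors' deposited table called this summary row higher in activated against control (log2 fold change 0.0874, adjusted p = 0.00895). Reads without a unique alignment made up 36.3% of each wild type library, above the 30.2% to 31.7% of the control libraries. This row had several solutions in the wild type group. Its equal shares in the 2 libraries follow from the rule that settled it, and only the group mean was given.

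In activated against control the authors' deposited table called 89.7% of its genes higher, with a median log2 fold change of 0.53 over genes with enough reads. Reads outside genes in the library totals do not account for this as the whole cause, because scaling by the reads on genes left the median at 0.48 (0.479). A few abundant genes could be part of it: the 50 most abundant genes held 28.3% to 30.0% of gene reads in activated and 39.6% to 41.7% in control libraries, and scaling without them gave a median of 0.22 (0.223), between the bounds of 0.1 and 0.25 set for that test. More mRNA per activated hepatocyte stays open as a biological explanation, because the tables hold no spiked-in reference, and the 46.9% of edgeR calls that were higher with TMM scaling follow from that scaling's assumption that most genes do not change. These last explanations cannot be told apart here, and the direction of genes near the median shift depends on the scaling.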

How the results depend on the processing

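Tests on the recovered reads (edgeR, DESeq2, camera, leaving out 1 library) and the peak counts outside input regions of either genotype were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the tables carry no column per library and the recovered reads no replicate number. The edgeR fits without a library leave 1 library in a group, which is assumed to vary like the other groups. Peaks near regulated genes (at 2, 10 and 50 kb) and peaks with a TCF motif were not run, since no mm9 annotation or genome was at hand, and leaving out input regions gives no value for peaks in input regions. With 2 libraries per group, depth and replication limit what genes with few reads can show.

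Of the 106 alternatives for counts and peak shares, 31 kept within 1.5 times the count or within the interval and 75 did not, and the cause was not tested except where fewer genes, libraries or peaks follow from the setting itself. At adjusted p below 0.01 the calls numbered 1283 in activated against control, 694 in null against wild type and 299 in control against wild type. With wild type in place of control, activated had 3783 and null 1117. edgeR gave, in the order activated against control, null against control, activated against null, activated, null and control against wild type, 646, 22, 1361, 1604, 69 and 0 calls (2537, 599, 3418, 3943, 1317 and 934 at an unadjusted p below 0.05), and DESeq2 1043, 84, 1645, 2197, 291 and 106. In the same order edgeR gave 1698, 25, 3912, 3237, 87 and 0 with the authors' totals, 1421, 147, 2231, 2991, 632 and 382 without the filter, and 227, 17, 1359, 1549, 184 and 0 with 2 groups. With the authors' totals 1505 of the 1698 were higher and 193 lower. Without 1 library the edgeR counts ranged from 249 (without control library B) to 628 (without activated B), from 9 (without null A or null B) to 33 (without control B), from 376 (without null A) to 1583 (without activated B), from 362 (without wild type B) to 1594 (without activated B), from 16 (without null A) to 38 (without wild type B), and from 0 (without control A, wild type A or wild type B) to 47 (without control B). Genes regulated in opposite directions numbered 157, and 18 by edgeR (174 and 28 against wild type). With a separate reference library for each mutant edgeR gave 12 and 26 against control and 23 and 19 against wild type. Of the 150 list results (25 lists, higher and lower, in the comparisons among activated, null and control) 46 passed. Camera, which gives 1 result per list, passed 34 with the preset correlation and 9 with an estimated one. The cell cycle list in activated against control, for example, had camera adjusted p = 3.69e-09 with the preset and 0.425 with the estimated correlation. Periportal genes in null against control had 3.37e-05 and 0.239.

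Of activated Tcf4 peaks 44.8% overlapped null Tcf4 peaks among the higher-scored peaks of each list, 37.9% with an overlap of at least 0.5 of the shorter peak, 21.6% outside input regions of the same genotype and 23.7% outside those of either. For β-catenin peaks in activated Tcf4 peaks these were 45.7%, 38.1%, 21.5% and 18.7%. In input regions lay 39.8% (higher-scored) and 32.5% (at least 0.5 of the shorter peak) of activated Tcf4 peaks, 28.8% and 25.3% of β-catenin peaks, and 22.9% and 20.8% of null Tcf4 peaks.

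For the genes named in the text, 1172 values under alternatives stayed on their side of the threshold (direction was compared only where a value passed in the authors' deposited table or under the alternative), 551 kept direction but no longer passed, 3 passed only under the alternative (Apc in activated against control with the authors' totals; Axin2 and Lgr5 in control against wild type without the filter), and 10 reversed, in each case without 1 library. In log2 fold change these were, in activated against control without activated B, Lcn2 (−0.74, highest 2.82 without activated A, and 2.44 in the authors' deposited table), Marco (−0.62, 4.63 without control A, and 3.16) and Cd5l (−0.53, 3.97 without control A, and 2.10). In null against control they were Myc without control A (1.13, lowest −2.51 without control B, and −1.69) and Cyp4a14 without control B (0.84, −3.22 without null A, and −2.38). In activated against null they were Ctnnb1 without activated A (−0.18) and without null B (−0.0128, highest 0.19 without activated B, and 0.61) and Cd5l without activated B (−0.0125, 2.90 without activated A, and 2.66). In control against wild type they were Cyp26a1 without wild type A (0.56, lowest −3.38 without control A, and −2.41) and Stab1 without control A (−0.0835, highest 2.57 without control B, and 1.72). The cause was not tested. These genes are a part, chosen after values were seen, of those the rule names; over all of these, 44 values reversed, 3324 stayed, 45 passed only under the alternative and 2134 no longer passed.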

Other observations

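Of the tests in this part, the ones on Kupffer markers were chosen after the result was seen, and the ones on clock genes were set before their result was seen, although the median clock gene of each wild type library was already known. Libraries of one group differed in acute phase and sex-biased genes. The acute phase gene Saa1 stood at 77.1 and 727 CPM in the activated libraries and at 646 and 22.1 CPM in the wild type libraries, and Lcn2, an iron-scavenging protein of the same list, at 84.4 and 1024 CPM and at 289.7 and 6.68 CPM. The female-biased Cyp2b9 stood at 52.9 and 1.85 CPM in activated, 7.85 and 112 CPM in control and 230.4 and 217 CPM in null libraries. Of the same list, the Y-linked Ddx3y stood at 25.2 to 49.8 CPM and Eif2s3y at 16.5 to 27.8 CPM over all libraries. Xist, expressed in female cells, stood at 0.259 CPM or less in every library. These values argue against a mix of sexes among the libraries. Alas2, which starts heme synthesis in red cell precursors, stood at 4.95 and 11.3 CPM in activated, 20.5 and 79.5 CPM in control and 102 and 169.7 CPM in wild type libraries. Hba-a1, Hba-a2, Slc4a1 and Gypa, of the same erythroid list, stood at 0.264 CPM or less in every library. Hba-a1 and Hba-a2 can share reads with each other. Reads without a unique alignment were not counted on genes, so the low values of these 2 genes are uncertain. Alas2 by itself therefore neither shows nor excludes a varying content of red cells.

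Kupffer cell markers were called higher in activated against control in the authors' deposited table (14 of 14), with 0 edgeR calls after its filter and adjusted p = 0.602 with an estimated correlation. A lower share of hepatocytes stays open: between these groups the edgeR log2 fold changes, none of which passed, had a median of 1.45 (quartiles 1.26 and 1.71) for Kupffer and 1.55 (1.24 and 1.77) for endothelial markers. Against it, library A minus B had medians of −2.97 for Kupffer and −0.84 (−0.838) for endothelial markers in the activated group, and of −1.03 and −2.09 in the null group, where the quartiles did not overlap either. Varying carry-over of Kupffer cells between isolations may account for the calls: the difference of −2.97 within the activated group exceeded the median between the groups, and the most abundant markers, Cd5l and Clec4f, stood at 59.99 and 34.4 CPM in activated library A and at 464 and 224 CPM in activated library B. An effect of β-catenin activation on Kupffer cells stays open too, because the median ranged from −0.87 (−0.866) without activated library B to 3.85 without control library A; no other list held the 14 Kupffer or the endothelial markers, 7 Kupffer and 11 endothelial markers reached 1 CPM in all 8 libraries, and the labels name no sort that would remove these cells.

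Clock genes were called lower in null against control in the authors' deposited table, with 2 of 17 higher and 9 lower, but with 0 edgeR calls and adjusted p = 0.341 with an estimated correlation (against wild type 1 higher and 11 lower, 0 by edgeR, adjusted p = 0.349 with an estimated correlation). Another time of day at hepatocyte isolation is a candidate explanation: over the 17 genes, null minus control followed wild type library A minus B (Spearman rho 0.919, permutation p = 1e-05, the smallest that 100000 permutations can give; Pearson r = 0.913, permutation p = 1e-05), although genes of one clock are not independent replicates. Dbp, for example, stood at 2.92 and 2.83 CPM in null, 113 and 24.2 CPM in control and 7.65 and 155 CPM in wild type libraries, and Arntl, which is active at the opposite phase, at 19.7 and 20.04, 0.753 and 8.70, and 15.2 and 1.11 CPM. Loss of β-catenin itself stays open, because both null libraries lay below all 4 control and wild type libraries for 7 of the 9 clock genes called lower, between the shares of 0.1 and 0.8 set for that test. The labels give no hour of isolation, so these explanations cannot be told apart.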
